A study of Mus musculus with 6 samples.

How the data were processed

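Total RNA from 6 samples of a stable mouse embryonic stem (ES) cell line was measured on Affymetrix arrays after biotin labelling. The line holds an inducible gene that is switched on by withdrawing tetracycline from the medium. Per the labels, 3 samples came from clones grown for 48 h without tetracycline (induced) and 3 from control clones kept in medium with tetracycline (uninduced). The labels number the samples of each group as biological replicates 1 to 3 and do not say whether each number is a separate clone or whether the 2 groups are the same clones grown in 2 media. The name of the induced gene is not given in the sources used here, so its level was not checked.

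The values analysed were the deposited log2 signals of 45101 probe sets, 1 column per sample. Per the submitters' processing notes, affy and RMA were used, with no version. RMA corrects the background, brings the arrays to a common distribution and sums up the probes of a set on the log2 scale. The deposited values ran from about 2.6 to 15.1, and the array medians lay between 5.19 and 5.23. Array images and detection calls were not used here, so a dim probe set cannot be told from an absent transcript. The number of arrays limits the precision.

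The 64 Affymetrix control probe sets were left out of the tests and examined apart, which left 45037. Gene symbols came from the platform annotation. It gave 1 symbol to 34945 probe sets, several to 932 and none to 9160. Of the first kind, 34741 matched the RefSeq table (assembly GRCm38.p6, used for names only) by gene identifier, and 0 symbols needed an update. No coordinates are given, since the genome build is not given in the sources used here. Each of the 18193 genes was represented by the probe set with 1 symbol and the highest mean signal over all 6 samples. More than 1 probe set existed for 9010 genes.

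Differences are induced minus uninduced. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 4 residual and 3.59 prior degrees of freedom) and tested on both sides. The p-values were adjusted by Benjamini-Hochberg over all 45037 probe sets, with calls at an adjusted p under 0.05 and no minimum fold. The error beside each log2 difference is the moderated standard error (SE). The design, the alternatives, the lists of genes and the rule for naming genes were chosen before the data were examined. That rule took the 14 genes with the largest rise and the 14 with the largest fall among called genes whose groups did not overlap. It added Pou5f1, Nanog and Sox2, and in each list up to 4 called members with the largest difference, which gave 142 genes, and the text describes a selection of them. Other members of the lists that the text names, either as exceptions to the direction of their list or as further examples of it (such as Bnip3, Slc2a1, Ldha, Atf4, Dusp4 and Dusp6), were chosen after their values were seen.

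The 32 lists held 776 measured genes, 32 of them in more than 1 list. Each list was tested with camera in limma, which compares its members with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. The lists covered the pluripotency network, formative and primed cells, 2-cell-like cells, germ layers and extraembryonic tissues, feeder fibroblasts, germline, imprinted and Hox genes, stress pathways, metabolism, ribosomes, the cell cycle, signalling pathways, apoptosis and chromatin regulators.

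The replicate numbers were checked for pairing before any fits were compared. After the group means were subtracted, the correlations of same-numbered samples across probe sets were 0.145, 0.172 and 0.139, and all 6 differently numbered pairs lay below 0. Subtracting the group means pushes the differently numbered pairs below 0 on average once the same-numbered ones are above 0. Those 6 values are thus no separate support for pairing. Pairing was thus only a possibility taken from the data, since every same-numbered pair passed 0.1. It was not tested, and the labels state no shared batch. A fit with the replicate number as a block was run beside the fit without it. Other alternatives left out each sample in turn, kept only the brighter probe sets, centred or quantile normalized the arrays again, weighted the arrays, changed the prior, the statistic or the minimum fold, or averaged the probe sets of a gene. Scaling to spike-in controls was added later.

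The fit was tested on simulated data. Among 45037 simulated probe sets compared as induced against uninduced, it recovered 37.9% of 58 changed by 0.5 on the log2 scale, 87.5% of 72 changed by 1 and 98.6% of 70 changed by 2. Of 160 calls, 6 were false and 0 had the wrong sign. The real comparison gave 8430 calls. With so few changed probe sets in the simulation, the adjustment demanded a smaller unadjusted p there. The recovery therefore does not give the sensitivity of the real comparison. In a simulated shift of 1 list by 0.5, camera called that list and 0 others. The simulated probe sets varied independently of each other. The simulation therefore does not test the preset correlation, on which the list calls depend. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.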

Results

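Transcript levels were measured in 3 induced and 3 uninduced samples of undifferentiated mouse ES cells, a cell type that self-renews and can form all tissues of the embryo. The comparison asks which transcripts differ after 48 h without tetracycline, when the inducible gene of this line is switched on. Tetracycline was present in every uninduced sample and in no induced sample, so the drug and the induction differ together. The labels also leave open whether the 2 groups are the same clones, so a difference between clones may be part of every value below. The 6 arrays had similar distributions, with medians between 5.19 and 5.23 on the log2 scale. Across probe sets, which are not independent replicates, the correlation between samples was 0.997 to 0.998 for the 6 pairs within a group and 0.992 to 0.994 for the 9 pairs between groups. The first principal component held 61.7% of the variance and separated the groups, followed by components with 11.8% and 10.6%.

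Genes that respond to low oxygen and enzymes of glycolysis and cholesterol synthesis were higher in induced cells. Genes of ribosome biogenesis and of the integrated stress response were lower, as were Myc and the immediate early gene Egr1. None of these lists was called with an estimated correlation (adjusted p = 0.384 for each in camera). The adjustment gives many lists this same value. Before it, the p-values in that test were 0.0254 for cholesterol synthesis, 0.0262 for hypoxia, 0.127 for ribosome biogenesis and 0.172 for the integrated stress response. Ccng2, a cyclin linked to cell cycle arrest, had the largest rise of a gene on its representative probe set, 2.56 ± 0.10 on the log2 scale (SE, n = 3 per group), or 5.89-fold. Skor1, a corepressor of the SKI family, fell from a mean log2 signal of 7.82 ± 0.57 (SD) to 4.83 ± 0.25 on 1 probe set (adjusted p = 0.000619 in limma), while its other, dimmer probe set differed by -0.03 (adjusted p = 0.907). The lower mean lies under the array medians, where a dim probe set cannot be told from an absent transcript, so the size of this fall is uncertain.

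Among the largest rises were also Ppp1r3c, which targets protein phosphatase to glycogen (log2 2.52 ± 0.17), the mitochondrial protein Ndufa4l2 (2.42 ± 0.11) and the transcriptional repressor Bhlhe40 (2.37 ± 0.11). The histone gene H2aw rose by 2.25, the early response gene Ier3 by 2.21, the glutathione transferase Mgst1 by 2.15, and the simple epithelial keratin Krt7 by 2.15. The meiotic recombination gene Meiob (2.11), the acyl-CoA thioesterase Acot1 (2.07), the germ cell kinase Aurkc (2.07) and Lrrc31 (2.06) rose to a similar extent. Adjusted p-values of these rises, from limma with Benjamini-Hochberg adjustment, ran from 0.000122 to 0.00148. The remaining genes with the largest rises, Egln3 and Aldoc, belong to the hypoxia list. Only 1 of 2 probe sets was called for each of Ppp1r3c, Mgst1 and Aldoc.

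Egr1, a zinc finger factor induced by growth signals, fell by 2.29 ± 0.18, from a mean log2 signal of 9.79 ± 0.29 (SD) to 7.50 ± 0.30. Id3, an inhibitor of basic helix-loop-helix factors and a BMP target, fell by 1.73 ± 0.10. Other large falls were those of 9330159F19Rik (-2.40), Tmcc3 (-2.23), Synpo2l (-2.00), Mcc (-1.80), the sphingomyelin synthase Sgms2 (-1.79) and Tmem125 (-1.76). Soga3, Kirrel and Gm11772 fell by 1.73 each and Clnk fell by 1.65. The histone gene H3f3b fell by 2.37 on the only probe set that carries its symbol alone. The induced mean there, 5.34, lies close to the array medians. Probe sets with several symbols or none were not examined for this gene, so a fall of its transcripts as a whole was not shown. Adjusted p-values of these falls in limma ran from 0.000122 to 0.00838. In 1 of the groups the signal lay under the array medians for Ppp1r3c and Meiob (uninduced) and for 9330159F19Rik, Tmcc3, Sgms2 and Gm11772 (induced), so the size of these changes is uncertain as well. Among the falls, only part of the probe sets was called for Mcc (2 of 5), Tmcc3 (3 of 5) and Synpo2l (3 of 4). The same held for Tmem125 and Kirrel (1 of 2 each), and 0 probe sets of these 5 genes were called higher.

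Of 45037 probe sets, 8430 (18.7%) were called by limma, 3742 higher and 4688 lower in induced cells. Most differences were small. The median size was 0.42 on the log2 scale, a fold of 1.34, and 468 called probe sets (5.55%) changed at least 2-fold, 254 higher and 214 lower. By representative probe set, 2007 genes rose and 2379 fell, and 126 of the 5442 genes with any called probe set had calls in both directions. The groups did not overlap in 8429 of the called probe sets, and in 36.8% of all probe sets against 10% by chance. The count was 5237 without uninduced replicate 2 and 5455 without uninduced replicate 3. When each array was scaled to its poly(A) spike-in controls, a setting chosen after the data were seen, the median difference of all probe sets moved from 0.02 to -0.23 and the calls became 908 higher and 11394 lower, against 3742 and 4688. Directions below therefore refer to the deposited normalization, and list tests compare members with the other genes on the array. List calls and list p-values are those of camera unless another test is named. Listed genes without a usable probe set were left out, so counts refer to measured members, as in 33 of 49 listed cytosolic ribosomal proteins. Measured here means that a probe set carries the symbol of the gene alone in the annotation used.

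Hypoxia and glycolysis genes rose together. Of 28 measured members, 25 rose and 1 fell, with 26 and 1 when adjusted over the list alone, and the median difference was 0.67. Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation, rose 4.19-fold (2.07 ± 0.12, adjusted p = 0.000239 in limma). The glycolytic enzyme Aldoc rose by 2.07 ± 0.09, the vasodilator peptide Adm by 1.95 ± 0.11 (and by 2.93 on a dimmer probe set) and Ankrd37 by 1.79 ± 0.08. The mitophagy receptor Bnip3 rose by 1.75, the glucose transporter Slc2a1 by 0.65 and lactate dehydrogenase Ldha by 0.48. The histone demethylase Kdm3a fell by 0.31, while Pdk1 (0.35) and Hk2 (-0.04) were not called. Camera gave an adjusted p of 2.59e-16, and adjusted p = 0.384 with an estimated correlation. After spike-in scaling 16 members were still higher and 1 lower.

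Cholesterol synthesis genes also rose. Of 20 measured members 17 rose and 0 fell, the same counts as when adjusted over the list alone, with a median of 0.54. Hmgcr, Ldlr, Dhcr24, Acat2 and Pcsk9 were listed but left out, since no probe set carried their symbol alone in the annotation used. The array may still hold probe sets for them. Insig1, a sterol-sensing regulator of the pathway, rose 2.04-fold (1.03 ± 0.09, adjusted p = 0.000542 in limma). Dhcr7, which catalyses the last step to cholesterol, rose by 1.00 ± 0.06, and the sterol demethylation enzymes Cyp51 and Msmo1 rose by 0.85 ± 0.06 and 0.84 ± 0.08. Ebp (0.02), Mvk (0.08) and Pmvk (0.17) were not called. Camera gave an adjusted p of 3.58e-11, and adjusted p = 0.384 with an estimated correlation. After spike-in scaling, 8 members were higher and 0 lower.

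Targets of p53 were higher as a list. Of 24 members, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.41. Ddit4, an inhibitor of mTOR signalling that also responds to hypoxia, rose by 1.66 ± 0.13. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 2.25-fold (1.17 ± 0.09, adjusted p = 0.000406 in limma), the BH3-only gene Pmaip1 rose by 0.97 ± 0.10 and Trp53inp1 by 0.78 ± 0.08. Sesn2, which is also an integrated stress response target, fell by 0.44, and Mdm2 was not called (0.22). Camera gave an adjusted p of 1.15e-05, and adjusted p = 0.384 with an estimated correlation. After spike-in scaling 5 members were higher and 2 lower.

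**Figure D1:**
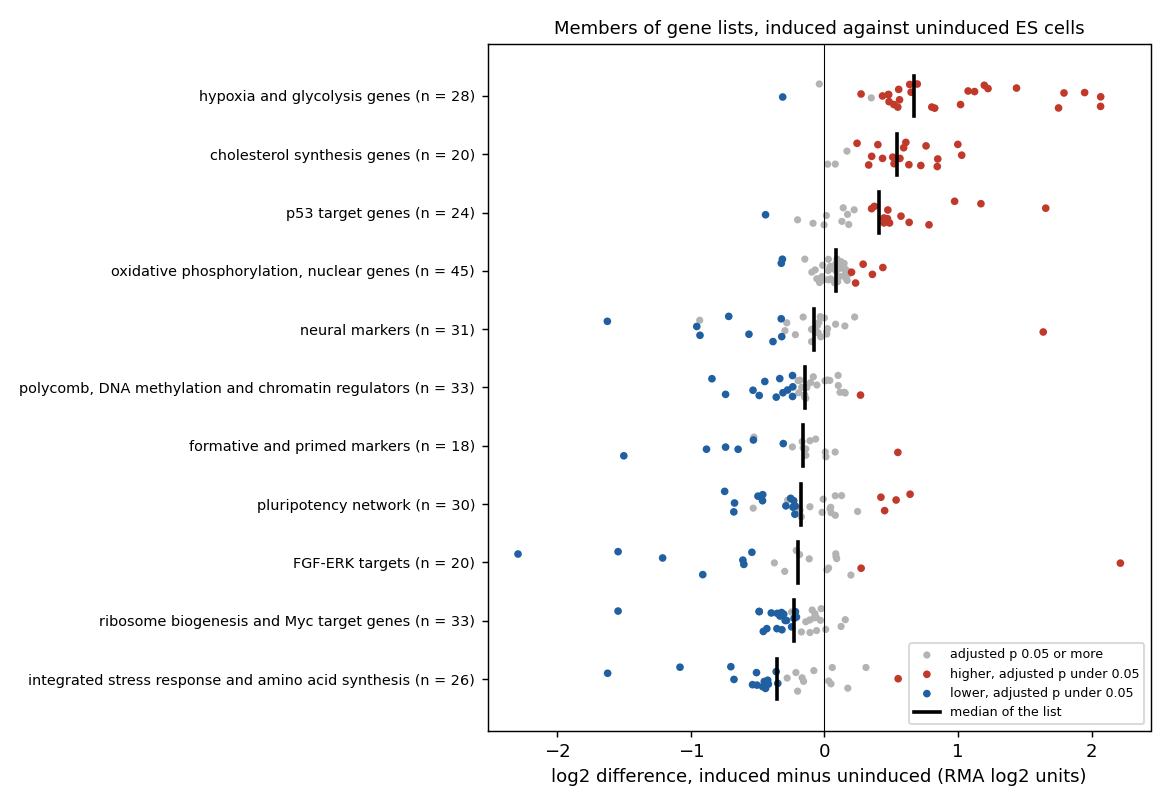
Log2 difference, induced minus uninduced, of each measured member of the 10 lists called by camera and of the pluripotency network. Each point is a gene, red or blue where it was called higher or lower, and black bars mark medians, which ran from -0.36 for the integrated stress response to 0.67 for hypoxia and glycolysis.

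Ribosome biogenesis and Myc target genes were lower. Of 33 members, 18 fell and 0 rose, with 20 and 1 when adjusted over the list alone, and the median was -0.23. Myc itself, which drives transcription of ribosome assembly genes, was 2.92-fold lower (-1.54 ± 0.10, adjusted p = 0.000253 in limma). The ribosome assembly factors Rrp12 and Bop1 fell by 0.49 each, with SEs of 0.08 and 0.06. Camera gave an adjusted p of 6.08e-07, and adjusted p = 0.384 with an estimated correlation. Of 33 cytosolic ribosomal proteins, 2 were higher and 2 lower (1 and 2 adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.516. Of the 29 members that were not called, 27 had a mean signal over 14, near the brightest value of 15.13, which limits the change that can be measured, while the 4 called ones, among them Rpl12 (0.67) and Rpl14 (-0.41), lay at 10.8 or below.

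Integrated stress response and amino acid synthesis genes fell as well. Of 26 members, 14 fell and 1 rose (17 and 1 adjusted over the list alone), and the median was -0.36. Chac1, a glutathione-degrading enzyme induced by Atf4, fell by 1.62 ± 0.09 to a level 3.08-fold lower (adjusted p = 0.000206 in limma). The transcription factor Atf5 fell by 1.08 ± 0.08, the pseudokinase Trib3 by 0.70 ± 0.08, the mitochondrial folate enzyme Mthfd2 by 0.68 ± 0.12 and Atf4 by 0.51. Ddit3, a stress-induced factor, rose by 0.55. Camera gave an adjusted p of 2.77e-05, and adjusted p = 0.384 with an estimated correlation. Endoplasmic reticulum chaperones and the unfolded protein response were not called by camera (adjusted p = 0.168, median -0.11), with 1 of 22 members higher and 5 lower (2 and 6 adjusted over the list alone). Herpud1, which acts in protein degradation at that membrane, fell by 0.71 ± 0.07. Heat shock genes had 1 of 19 members higher and 6 lower, the same when adjusted over the list alone, a median of -0.07 and an adjusted p of 0.0624 that became 0.0422 without uninduced replicate 3. The chaperone genes Chordc1 and Hsph1 fell by 0.79 ± 0.06 and 0.72 ± 0.06.

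FGF-ERK targets were lower as a list (camera adjusted p = 0.0310). This call had adjusted p = 0.384 with an estimated correlation, and 0.181 among the brighter probe sets. Of 20 members, 7 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.20. Besides Egr1 and Myc, the fall included Phlda1 (-1.21 ± 0.11) and the ERK phosphatases Dusp4 (-0.91) and Dusp6 (-0.54), while Ier3 (2.21 ± 0.09) and the feedback inhibitor Spry1 (0.27) rose. Of 33 polycomb, DNA methylation and chromatin regulators, 12 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.15, a camera adjusted p of 0.000888, and adjusted p = 0.384 with an estimated correlation. The de novo DNA methyltransferase Dnmt3b fell by 0.74 ± 0.10 and the polycomb gene Cbx2 by 0.53 ± 0.08, and the demethylase Kdm5b rose by 0.27.

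Markers of formative and primed cells, the stage that follows naive pluripotency, were lower, with 6 of 18 members lower and 1 higher, the same counts as when adjusted over the list alone. The median was -0.16 and the camera adjusted p was 0.0129, with adjusted p = 0.384 with an estimated correlation and 0.0680 among the brighter probe sets. N-cadherin (Cdh2) fell by 1.50 ± 0.09 and Pou3f1 by 0.88 ± 0.12, the Wnt antagonist Sfrp2 rose by 0.55, and Fgf5 was not called (0.08). Of 31 neural markers, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 0.0310. This call had adjusted p = 0.384 with an estimated correlation, 0.0577 without uninduced replicate 1 and 0.0796 without induced replicate 2. Pax6, a regulator of neural and eye development, fell by 1.63 ± 0.18 and neuron-specific tubulin Tubb3 by 0.93 ± 0.07, while Neurod1, a neuronal differentiation factor, rose 3.11-fold (1.64 ± 0.14, adjusted p = 0.000513 in limma).

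Nuclear genes of oxidative phosphorylation were slightly higher than other genes (camera adjusted p = 0.0285, and adjusted p = 0.410 with an estimated correlation), with 5 of 45 members higher and 2 lower (4 and 1 adjusted over the list alone). The median was 0.08, which became -0.16 after spike-in scaling, with 0 members higher and 3 lower. The call was lost without uninduced replicate 1 (adjusted p = 0.0577) and without induced replicate 2 (0.0671). The complex II subunit Sdhc had a difference of 0.44 ± 0.06, not called after spike-in scaling (adjusted p = 0.305), and the ATP synthase gene Atp5g1 fell by 0.32 ± 0.06 on 1 of its 2 probe sets, a call lost in the mean of both (-0.07, adjusted p = 0.613). Mitochondrial ribosome and translation genes showed 3 of 44 members higher and 5 lower, also when adjusted over the list alone, with a camera adjusted p of 0.637 on the lower side, a mean of -0.02 and a median of 0.02. Among the latter, Mrpl20 fell by 0.33 ± 0.06.

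Pou5f1 had a mean log2 signal of 13.84 ± 0.07 (SD, n = 3) in uninduced and 13.73 ± 0.02 in induced samples, a difference of -0.11 ± 0.06 (adjusted p = 0.281 in limma). The groups did not overlap, and a trended robust prior called the difference (adjusted p = 0.0228). Nanog differed by 0.08 ± 0.07 (adjusted p = 0.472) and Sox2 by 0.05 ± 0.08 (adjusted p = 0.753). Across the pluripotency network 12 of 30 members fell and 4 rose (15 and 5 adjusted over the list alone), the median was -0.18, and camera did not call the list (adjusted p = 0.0624, or 0.0388 without induced replicate 1). The nuclear receptor Nr5a2 fell by 0.75 ± 0.07, Zfp281 by 0.68 ± 0.09 and the RNA-binding protein Lin28a by 0.67 ± 0.08. The growth factor gene Fgf4 rose by 0.64 ± 0.07, Tdgf1 by 0.54, Klf2 by 0.45 and Klf4 by 0.42. LIF-STAT3 targets split into 4 higher and 5 lower of 15 (4 and 6 adjusted over the list alone), with Stat3 lower by a log2 difference of -0.52 ± 0.08. Their median was 0.03, their mean -0.02 and the camera adjusted p 0.997.

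**Figure D2:**
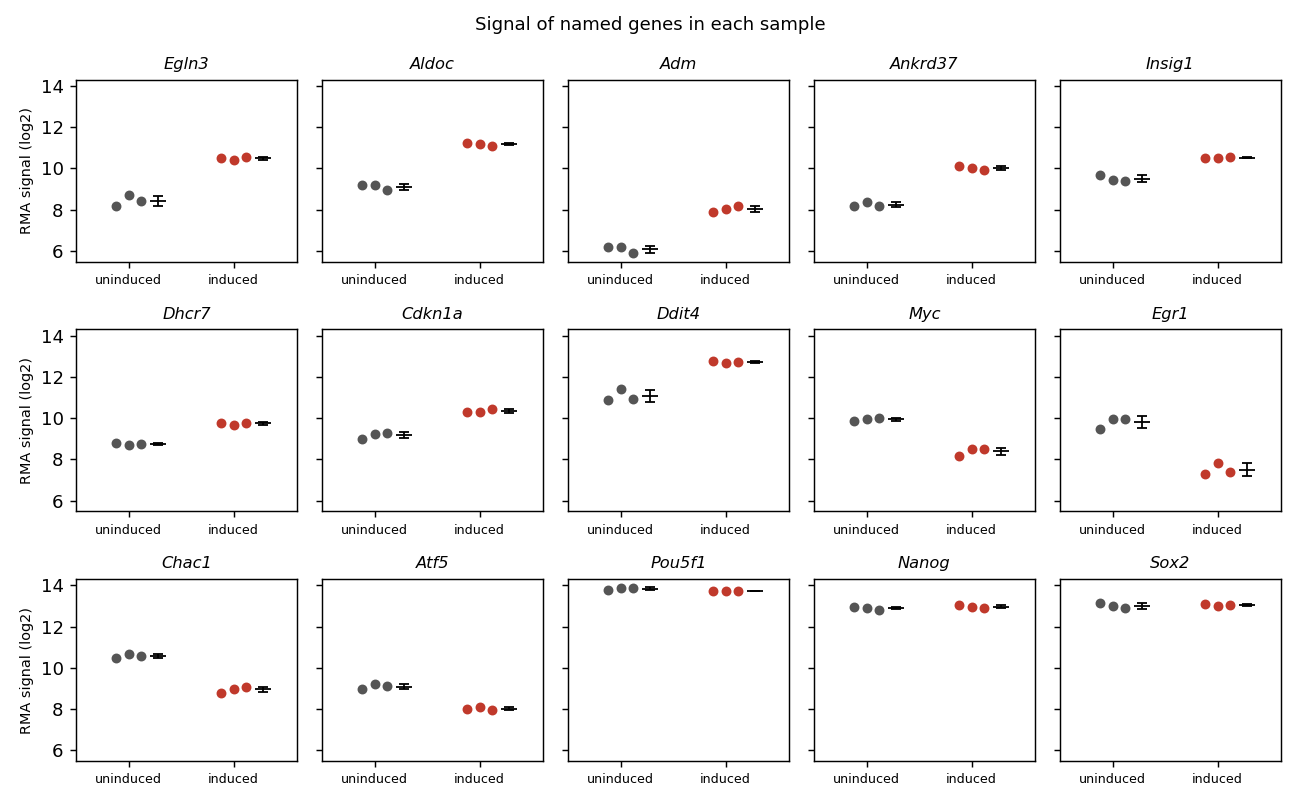
RMA signal (log2) of 15 genes in each of the 3 uninduced and 3 induced samples, with the group mean and SD beside the points. Egln3, Aldoc, Adm and Ankrd37 were higher in all 3 induced samples, Myc, Egr1, Chac1 and Atf5 were lower, and Pou5f1, Nanog and Sox2 lay near 13 to 14 in both groups.

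No list of lineage markers besides the neural and formative ones was called by camera, while fry, which does not compare members with other genes, also called the primitive streak and fibroblast lists (adjusted p = 0.00495 each). Primitive endoderm markers had 3 of 26 members higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.749, on the lower side, mean -0.03, median 0.03). Keratin Krt19 rose by 1.22 ± 0.08 and laminin Lama1 fell by 0.80 ± 0.10. Primitive streak and mesoderm markers had 0 of 23 higher and 3 lower by either adjustment (over all probe sets or adjusted over the list alone), a median of -0.01 and an adjusted p of 0.213, with Evx1 lower. Its induced mean of 5.02 lies under the array medians, so the size of its fall is uncertain. Trophectoderm markers had 2 of 20 higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.657, on the lower side, median -0.07, mean 0.0046), with Krt7 and Ascl2 (1.32 ± 0.14) among the rises and Krt8 among the falls (-0.82 ± 0.10). The 2-cell-like list had 0 of 13 measured members higher and 1 lower (Zfp352, -0.39 ± 0.08), also when adjusted over the list alone, with an adjusted p of 0.864, a median of 0.02 and a mean of -0.05. Of its 22 listed genes 9 had no usable probe set in the annotation used, among them Zscan4c, Zscan4d and Zscan4f, so their levels are unknown here. Zfp352 lay under the array medians in both groups, and its call was lost in the mean of its 2 probe sets (-0.21, adjusted p = 0.0721) and without moderation (adjusted p = 0.0594). Fibroblast markers, a check for feeder cells, had 4 of 27 higher and 3 lower, also when adjusted over the list alone, a median of 0.05 and an adjusted p of 0.538. Of these, Mmp2 rose by 1.11 ± 0.11 and Pdgfrb by 1.10 ± 0.09, while the collagen genes Col1a1 (-0.06), Col1a2 (0.08) and Col3a1 (-0.14) were not called, where Col1a1 and Col3a1 lay under the array medians in both groups.

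Germline genes had 4 of 23 members higher and 2 lower (4 and 3 adjusted over the list alone), an adjusted p of 0.749 on the higher side, a median of -0.01 and a mean of 0.07. Stra8, which licenses entry into meiosis and is induced by retinoic acid, rose 3.67-fold (1.87 ± 0.09, adjusted p = 0.000128 in limma), Dmrt1 rose by 0.87 ± 0.12 and the synaptonemal complex gene Sycp3 by 0.78 ± 0.08. Retinoic acid targets, among them Stra8, split into 3 higher and 3 lower of 17, also when adjusted over the list alone (adjusted p = 0.391, median 0.07), with Crabp1 at 1.05 ± 0.17. Meis2 was lower by an uncertain amount, since its induced mean of 4.95 lies under the array medians. Of 27 imprinted genes 1 rose and 6 fell (4 and 7 adjusted over the list alone), with a median of -0.03 and an adjusted p of 0.397. The falls included the maternally expressed noncoding RNAs Mirg (-1.14 ± 0.08), Meg3 (-0.89 ± 0.08) and Rian (-0.66 ± 0.13) of the Dlk1-Meg3 cluster. Mest, expressed from the paternal allele, fell by 1.00 ± 0.08. Hox genes had 2 of 33 higher and 1 lower (1 and 0 adjusted over the list alone), a median of 0.05 and an adjusted p of 0.377. Hoxb13 differed by 0.56 ± 0.09, to a mean signal of 4.85, and was not called after spike-in scaling (adjusted p = 0.0891). The other called members were dim as well. Hoxd13 went from a mean signal of 5.05 to 5.38, and its call was lost in the mean of its 2 probe sets. Hoxb1 went from 3.40 to 3.08, so the Hox counts rest on signals near or under the array medians.

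Notch targets and components had 6 of 17 members higher and 1 lower, also when adjusted over the list alone, with a median of 0.09 and an adjusted p of 0.0968 that became 0.00182 after spike-in scaling, with 4 members then higher and 4 lower. The ligand gene Dll1 rose 3.25-fold (1.70 ± 0.11, adjusted p = 0.000276 in limma), Hes6 by 1.16 ± 0.13 and the receptor Notch3 by 0.81 ± 0.06. BMP and Nodal-TGF-beta targets moved both ways, with 7 of 21 higher and 5 lower (7 and 7 adjusted over the list alone), a median of -0.05 and an adjusted p of 0.997. The Nodal antagonist Lefty1 rose by 1.44 ± 0.09, and Ccn2 (-0.86 ± 0.10) fell together with Id3. Tgfb1 also fell, by an uncertain amount, since its induced mean of 5.10 lies under the array medians. Wnt targets had 1 of 18 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.213, median -0.05), with Sp5 at -0.89 ± 0.15.

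Apoptosis regulators had 7 of 21 members higher and 3 lower (10 and 3 adjusted over the list alone), a median of 0.18 and an adjusted p of 0.236. Casp6, an executioner caspase, rose by 1.05 ± 0.09 and the BH3-only gene Bcl2l11 fell by 1.00 ± 0.07. Interferon-stimulated genes had 8 of 24 higher and 2 lower (8 and 4 adjusted over the list alone), a median of 0.08 and an adjusted p of 0.213. The antigen-presenting H2-K1 rose by 1.05 ± 0.09, and the RNA sensor Ddx58 fell by 1.17 ± 0.08. Genes of G2/M and mitosis had 6 of 29 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.06, adjusted p = 0.130), with Cenpe lower by a log2 difference of -0.45 ± 0.07. Ccnb2, a mitotic cyclin, differed by 0.43 ± 0.06, not called after spike-in scaling (adjusted p = 0.323). Genes of G1/S and DNA replication had 3 of 29 higher and 1 lower (2 and 1 adjusted over the list alone), a median of 0.05 and an adjusted p of 0.236. The fall was that of Tyms, called on 1 of 4 probe sets, with an induced mean of 4.96 under the array medians. The rise of E2f1 (0.25) was lost with the replicate block (adjusted p = 0.0959 in limma). After spike-in scaling the counts of higher and lower members became 2 and 6 for apoptosis regulators, 3 and 5 for interferon-stimulated genes, 0 and 4 for G2/M and mitosis and 0 and 4 for G1/S and DNA replication. They became 3 and 8 for germline genes, 0 and 6 for Hox genes, 2 and 7 for fibroblast markers, 3 and 9 for BMP and Nodal-TGF-beta targets and 3 and 4 for retinoic acid targets, so the balance of these counts depends on the scaling. They became 0 and 6 for LIF-STAT3 targets, 0 and 13 for mitochondrial ribosome and translation, 2 and 10 for primitive endoderm, 2 and 9 for trophectoderm, 0 and 8 for primitive streak and mesoderm, 0 and 5 for 2-cell-like, 1 and 16 for pluripotency, 0 and 11 for imprinted, 1 and 7 for Wnt and 1 and 2 for cytosolic ribosomal protein genes. In the stress lists they became 0 and 19 (integrated stress response), 0 and 11 (endoplasmic reticulum) and 1 and 7 (heat shock). For the other lists called lower they became 0 and 21 (ribosome biogenesis), 0 and 21 (polycomb and chromatin), 1 and 12 (FGF-ERK), 0 and 12 (formative) and 1 and 13 (neural). The medians of the lists for hypoxia and glycolysis (0.42), cholesterol synthesis (0.29) and p53 targets (0.16) were then above 0, and those of all others lay between -0.60 and -0.064.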

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

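The tests on tetracycline in the control medium and on the hybridization controls, and the scaling to spike-in controls, were chosen only after the result was seen.

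Control probe sets for bacterial poly(A) transcripts, which the Affymetrix protocol adds to RNA before labelling, gave a signal outside the main measurement. Over 24 probe sets the mean log2 signal was 6.65 ± 0.08 (SD, n = 3) in uninduced and 6.90 ± 0.14 in induced samples, a difference of 0.25 ± 0.09 (SE), with all 3 induced samples above all 3 uninduced ones (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). Hybridization controls, which are added after labelling, differed by 0.032, below the spike-ins by 0.22 ± 0.07, which argues against an array or hybridization effect on all controls alike. These controls are far brighter, with a mean of 11.35 in uninduced samples. They therefore cannot tell whether an effect was limited to dim probe sets. A larger amount of spike-in per sample, less endogenous poly(A) RNA per total RNA in induced cells and an effect on dim probe sets could each give the spike-in difference. These values do not separate them, nor do the labels say how much spike-in was added. Of the 5 classes of controls, 2 more parted the groups, in the other direction and also with p = 0.1 in the exact permutation test, 18S ribosomal RNA (-0.27 ± 0.11) and B1 and B2 repeats (-0.24 ± 0.06), and no biological explanation was tested.

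The rise of hypoxia and glycolysis genes in induced cells may reflect the induction, the medium, a difference between clones or the composition of the cultures. A lower content of endogenous poly(A) RNA would need the rise to vanish after scaling to the spike-ins. The median of the list was then still 0.42 ± 0.15 (SE over members, without the error of the spike-ins). That scaling lowers the difference of every gene by the same 0.25 ± 0.09 (SE), so the outcome followed from the list median of 0.67. It shows only that the spike-in difference is smaller than the rise, and is no separate test. Feeder fibroblasts would bring their abundant transcripts, yet the fibroblast list had a median of 0.046, below that of the hypoxia list by 0.63 ± 0.16. This SE is over members, not samples. The gap argues against feeders as the source of a rise of this size. A small difference in feeders stays open, since 4 of 27 members were higher and 3 lower, and fry called the list (adjusted p = 0.00495). Col1a1 (-0.06), Col1a2 (0.08) and Col3a1 (-0.14) were not called, but Col1a1 and Col3a1 are dim in both groups and add little. Tetracycline, which inhibits mitochondrial translation, stays open, because it would stress the control cells and the integrated stress response list was lower in induced cells (median -0.36 ± 0.09, camera adjusted p = 2.77e-05, but adjusted p = 0.384 with an estimated correlation, and another split of the samples gave a smaller unadjusted p), but drug and induction cannot be told apart where they always differ together. The induced gene itself, a difference between the clones of the 2 groups, and culture density or oxygen, about which the labels say nothing, remain untested hypotheses.

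More probe sets were called lower (4688) than higher (3742), and a technical source could lie in the RNA or in the scaling. A difference in RNA integrity would part the 3-prime and 5-prime control probe sets, whose distance differed between the groups by at most 0.065 (Actb), but these probe sets have a mean signal of 14.5 near the brightest value of 15.13, which compresses that distance and leaves integrity open. Loss of signal from unspliced or unannotated sequence would make probe sets without a gene symbol lower more often, whereas 46.8% of 776 such calls were lower against 56.6% of 7494 with 1 symbol, a gap of -9.83 percentage points. That source stays open all the same, because the B1 and B2 repeats, found largely in such sequence, were lower (-0.24 ± 0.06), and a probe set without a symbol is only unnamed in the table used. The scaling stays open too, as does the induction, since the share of higher calls was 44.4% as deposited and 7.38% after scaling to the spike-ins.

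The 6 samples can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 8430 called probe sets in limma and the highest of the others 0, with 873 to 1820 probe sets at an unadjusted p under 0.05 in those splits against 14243 in the real one. For lists called by camera the numbers were 10 and 8, so 1 of 10 splits reached the real value in either case. Of the other splits, 3 part all 3 replicate pairs as the real one does and gave 3, 3 and 8 called lists, and the other 6 part 1 pair and gave 2 to 8. For the integrated stress response, neural and formative lists another split gave a smaller camera p than the real one (9.87e-07 against 4.33e-06, 5.00e-05 against 0.00968 and 0.00184 against 0.00282). For hypoxia the smallest other p was 3.92e-07 against 8.09e-18, and for cholesterol synthesis 4.49e-05 against 2.24e-12. Every other split mixes the groups, which adds the group difference to its residual spread, so few called probe sets were built in. List tests in those splits still carry part of that difference. The other splits are thus no measure of chance.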

How the results depend on the processing

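Scaling to the spike-ins was chosen after the data were seen. The count of 8430 called probe sets lay between 8242 and 10593 when arrays were centred, quantile normalized again or weighted, when dim probe sets were left out, and with a trended robust prior. It was 12302 after spike-in scaling, with 7.38% higher, because that setting moves every probe set of an array by 1 amount. With the replicate block it was 7390, of which 6788 were among the 8430. Leaving out 1 sample at a time gave 5237 to 7194. Fewer calls came from a statistic without moderation (5540), the mean of all probe sets of a gene (4707) and 1 probe set per gene (5224), where fewer features were tested in the last pair, and from a minimum of 1 on the log2 scale (468) or a test against a fold of 1.2 (1730), which are stricter by construction.

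The 10 lists called by camera became 7 to 10 over the settings other than an estimated correlation and fry, and 8 to 11 when 1 sample was left out. With an estimated correlation 0 lists were called, since that setting allows for genes of a list varying together. Camera then gave 3 lists an unadjusted p under 0.05, cholesterol synthesis (0.0254), hypoxia and glycolysis (0.0262) and FGF-ERK targets (0.0473). Fry, which tests whether members move on balance 1 way without comparing them with other genes, called 23. The hypoxia, cholesterol, p53, ribosome biogenesis, stress response and polycomb lists were called in every setting but the estimated correlation. Quantile normalization ended the FGF-ERK call (adjusted p = 0.0529), as did gene means (0.103) and ranks (0.0834). Centring ended the oxidative phosphorylation call (0.0650), as did spike-in scaling (0.408). Array weights and gene means ended the neural call (0.0544 and 0.0558), as did leaving out dim probe sets (0.174), while gene means brought the heat shock list past the threshold (0.0232). The cause was not tested.

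Of 142 named genes, 121 had the same call without each sample in turn. The replicate block ended the calls of Sox7 (adjusted p = 0.0740), Bmp4 (0.0529), Tfap2a (0.0523) and E2f1 (0.0959) and changed no other call of a named gene or list. Spike-in scaling ended 14 calls and turned E2f1 to -0.00190. The mean of all probe sets turned Mrpl15 to -0.12 (adjusted p = 0.174), where 3 of its 8 probe sets were called higher and 2 lower. It also ended the calls of Atp5g1 (-0.07, adjusted p = 0.613) and Zfp352 (-0.21, 0.0721). Other named genes were also called on only part of their probe sets, such as Pax6 (2 of 5) and Pdgfrb, Bop1 and Casp6 (1 of 2 each). Printed differences are those of the representative probe set. The statistic without moderation ended those of Zfp352, Gm11772, Evx1, Rian, Mthfd2, Rpl12, Sp5 and Crabp1, among others (adjusted p = 0.0513 to 0.0829 for these 8). A trended robust prior called Pou5f1 lower (-0.11, adjusted p = 0.0228). Signals near the lower end of the scale limit what can be said of dim genes.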

Other observations

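No test in this part was chosen after its result was seen, but the single genes named here, apart from Ccng2 and Ppp1r3c, were chosen after their values were seen. Among families of 15 or more genes that share a symbol stem and lie outside the fixed lists, 121 were tested with camera and 5 were called, all lower in induced cells. Zinc finger genes named Zfp were the largest of the 5 called families, with 101 of 331 lower and 25 higher and a median of -0.14 (adjusted p = 0.000116, and adjusted p = 0.335 with an estimated correlation). Of 15 Integrator subunits, which cut noncoding and nascent transcripts, 6 were lower and 0 higher, with a median of -0.21 (adjusted p = 0.00458, and adjusted p = 0.692 with an estimated correlation), and Ints6 fell by 0.63 ± 0.06. The Ddx family of RNA helicases had 8 of 33 lower and 1 higher (median -0.18, adjusted p = 0.0110), genes with the Cdk stem 7 of 24 lower and 0 higher (median -0.21, adjusted p = 0.0112) and RNA-binding Rbm genes 12 of 36 lower and 3 higher (median -0.17, adjusted p = 0.0238). Each of these 3 had adjusted p = 0.692 with an estimated correlation. Cdk6, a kinase of the G1 phase, fell by 1.53 ± 0.16, and Cdk12 and Cdk13, which act on RNA polymerase, by 0.49 ± 0.07 and 0.54 ± 0.07. With an estimated correlation camera called 0 families, and 7 of 121 had an unadjusted p under 0.05. Carbonic anhydrases outside the hypoxia list were not called as a family (adjusted p = 0.0583), with 6 of 15 higher, 0 lower and a median of 0.34, among them Car12 (0.80 ± 0.12) and Car8 (0.68 ± 0.12), whose uninduced signal lies under the array medians and leaves the size uncertain.

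The genes for the oxygen-regulated factors themselves did not rise with the hypoxia list. Hif1a differed by -0.06 ± 0.06 (adjusted p = 0.571 in limma), and Epas1, which encodes the second such factor, fell by 1.00 ± 0.15 (adjusted p = 0.00384). These are RNA levels. The proteins, which are also controlled by degradation, were not measured, so the activity of the factors stays open.

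Ccng2, Pik3ip1 (1.83 ± 0.14), Pdk4 (1.78 ± 0.13) and Klhl24 (1.03 ± 0.08) rose, and all are reported targets of FoxO factors, so FoxO targets may be higher as a group. In 26 other FoxO targets, listed before their values were seen, 9 were higher and 2 lower, with a median of 0.039, and camera did not pass (p = 0.149, or 0.182 with an estimated correlation). Gadd45b (1.09 ± 0.14), Cdkn1b (0.96 ± 0.11) and Txnip (0.85 ± 0.06) rose, whereas Irs2 (-0.81 ± 0.15) and Foxo1 (-0.50 ± 0.07) fell, so the hypothesis stays open.

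Glycogen metabolism was examined in the same way, because Ppp1r3c, the glycogen phosphorylase gene Pygl (1.74 ± 0.13) and the phosphoglucomutase gene Pgm1 (1.76 ± 0.06) rose. Of 19 other genes of glycogen synthesis and breakdown, 6 were higher and 2 lower, with a median of 0.11, and camera did not pass (p = 0.139, or 0.305 with an estimated correlation). Ppp1r3b rose by 1.52 ± 0.13 and the branching enzyme Gbe1 by 1.00 ± 0.09, while Nhlrc1 and Phkb fell by 0.67 ± 0.08 and 0.33 ± 0.07, so a rise of the whole pathway was not shown. The size is uncertain for Ppp1r3c, Ppp1r3b and Nhlrc1, which lay under the array medians in 1 group.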
